A study of Mus musculus with 8 samples.

How the data were processed

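Single-cell RNA-seq was made from tumours of 4 KPC mice, each giving a viable and a fibroblast-enriched library, with 10x Chromium version 2 chemistry per the labels' protocols. Reads were processed with Cell Ranger 1.2.0 against the mouse build mm10 (GRCm38), per the submitters' processing notes. Each fraction was deposited as a table of genes by cells in which the ending of a cell name tells the mouse. The deposited values were on a natural log scale. They matched the natural log of 1 plus a cell's UMI count of a gene divided by the cell's total and multiplied by a constant, 5980 in the viable and 10446 in the fibroblast-enriched table. This form was read from the values, since no label states it. The deposited tables were already filtered for genes and cells, by filters that no label states.

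UMI counts were recovered by inverting that transformation, and 100% of values above 0 lay within 0.05 of a whole number. The viable table held 13813 gene identifiers, 13789 of them with a symbol, and that of the fibroblast-enriched fraction held 14330, of which 14307 had a symbol. Both tables held 13007 genes, and 806 and 1323 were in only the viable or only the enriched table. Comparisons across fractions used the shared genes, so a gene absent from a table was not read as 0. Gene positions came from GENCODE release M21 on GRCm38. Totals and cell numbers of each library open the results, and intervals of counts or shares were exact Poisson or Wilson 95% intervals.

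Cells of both fractions were clustered together on 2000 variable genes, 30 principal components and 20 nearest neighbours with the Leiden method at resolution 1. Fibroblast-like cells were clustered again at resolution 0.5. All members of 17 fixed gene lists were left out of the genes of this second clustering only. The first clustering, which set the fibroblast-like and immune classes, could use them. Clusters were named from 20 fixed sets of marker genes, with at least 3 detected markers of a set leading. The lists, the marker sets, the comparisons and all but the added alternatives were chosen before the data were examined. The scoring that turns markers into a name was set after the clusters had been seen. The fibroblast-enriched table lacks all 7 T-cell markers and 4 of 9 dendritic markers, so those classes rest on the viable cells they clustered with. The markers used for apCAF-like cells hold no MHC class II gene. A name ending in "-like" refers to marker RNA only.

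For each library and class with at least 10 cells, the mean UMIs per 10000 UMIs of a cell was taken over cells, and log2(mean + 0.1) was compared with limma, with an intensity trend in its empirical Bayes step and Benjamini-Hochberg adjustment at 0.05, two-sided. A test on counts had been planned for tables of counts, and limma on the log scale for tables of log values, which is what these were. Genes with a mean of at least 0.1 UMIs per 10000 over the libraries were tested, and comparisons between fibroblast classes left out the clustering genes. Gene lists were tested with camera, at a preset correlation of 0.01 and with an estimated correlation, and with fry. Shares of cells were compared with exact two-sided permutation tests over libraries. The share of cells with a UMI was also taken after thinning each cell to 3000 UMIs.

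Genes named in the text were chosen per comparison by a fixed rule. They were the detected sort antigens and MHC class II genes, the 8 largest rises and 8 largest falls past the threshold that moved the same way in every mouse, and up to 4 members of each list with the largest change past the threshold. Marker genes and pooled UMI counts of co-stimulatory genes were given in addition.

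Libraries with the same number come from the same animal per the labels, so the numbers pair them, and a fit with the mouse as a block was an alternative. Deviations from the group means correlated between same-numbered libraries at 0.462, -0.106, 0.163 and 0.351 for mice 1 to 4 in the fractions, and between 0.161 and 0.370 for apCAF-like against other fibroblast-like cells.

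The limma step was tested on simulated data with known changes. Every simulated gene had the same spread between libraries, set from the median standard error of the real fit, and no mouse effect. The rates therefore overstate recovery for genes with a wider spread. For the fractions, 53.7%, 100% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered over 8164 genes. For apCAF-like against other fibroblast-like cells the values were 26.9%, 70.1% and 100% over 8065 genes. For fibroblast-like cells between fractions they were 20.9%, 74.6% and 100% over 8076 genes, with 7.14% of calls false.

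Alternatives were the mouse as a block, no filter on low levels, pseudocounts 10 times smaller and larger, each mouse left out, other clustering resolutions and numbers of variable genes, cells with immune-gene UMIs left out, cells under 1000 genes left out, thinned cells and the fibroblasts of the viable fraction. Added after the values were seen were median centring, naming by the subtype score alone, the apCAF-like cells left out, the fibroblast-enriched library of mouse 3 left out, cells over 20% mitochondrial UMIs left out and shares among named classes other than ductal-like. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.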

Results

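Single-cell RNA was measured in pancreatic tumours of 4 KPC mice, a genetic model in which mutant Kras and mutant Trp53 drive ductal adenocarcinoma. Each tumour gave 2 droplet libraries. The viable fraction held cells sorted only for exclusion of the dye DAPI, and the fibroblast-enriched fraction held DAPI-negative cells that also lacked surface CD45, CD31 and EpCAM, the usual antigens of leukocytes, endothelial cells and epithelial cells. The viable libraries of mice 1 to 4 held 2965, 2147, 3418 and 2730 cells with totals of 19705303, 10993808, 25013260 and 23416978 unique molecular identifiers (UMIs). The fibroblast-enriched libraries held 1431, 2574, 345 and 4174 cells with 12783884, 33524745, 4530569 and 55860627 UMIs. Median UMIs per cell ran from 3540 to 7042 in the viable libraries and from 7232 to 12974 in the fibroblast-enriched ones. Levels below are mean UMIs per 10000 UMIs of a cell, averaged over the cells of a library, with the SD over libraries. Changes are differences of log2(level + 0.1) with their standard errors, a scale that understates changes of genes with low levels.

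The first comparison asked which cells the sort removed and which it enriched. Fibroblast-like cells made up 52.0% ± 15.0 (SD, n = 4) of the fibroblast-enriched libraries and 1.97% ± 1.58 of the viable ones. Macrophage/monocyte-like cells made up 60.4% ± 14.4 of the viable libraries and 0.798% ± 1.22 of the enriched ones. Ductal-like cells, the epithelial class, made up 40.1% ± 18.7 of the enriched libraries and 6.30% ± 3.23 of the viable ones. Shares add up to the whole, so removal of the immune cells raises the share of every other class. Pericyte-like cells, the mural cells of vessels, rose from 0.288% ± 0.226 to 5.77% ± 3.76.

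Dendritic-like cells held 6.07% ± 2.57 of viable cells and 0.289% ± 0.396 of enriched cells. T/NK-like cells held 2.11% ± 1.38 against 0.1249% ± 0.148, and B-cell/plasma-like cells 1.84% ± 1.77 against 0.0996% ± 0.130. Endothelial-like cells held 0.605% ± 0.181 of viable cells, and 0 of the 8524 cells of the enriched libraries fell in that class. Cells in clusters that met no naming rule made up 6.65% ± 3.99 and 0.184% ± 0.274. Some small means rested on a single library. Without mouse 3 the enriched share was 0.195% for macrophage/monocyte-like, 0.0958% for dendritic-like, 0.0699% for T/NK-like, 0.0362% for B-cell/plasma-like and 0.0518% for unnamed cells, and without mouse 1 the viable share of B-cell/plasma-like cells was 0.958%. Without mouse 4 the viable shares of fibroblast-like and pericyte-like cells were 1.29% and 0.188%. Of 11 classes tested, 9 differed at p = 0.0286 by a two-sided exact permutation test, the smallest value that 4 against 4 libraries can give, with an adjusted p of 0.0349. The 3 higher classes were fibroblast-like, pericyte-like and ductal-like, and each difference had the same direction in all 4 mice. Neutrophil-like cells (13.3% ± 20.8 viable, 0.515% ± 0.735 enriched, exact permutation p = 0.0571, adjusted p = 0.0629) and acinar-like cells (0.489% ± 0.282 and 0.130% ± 0.129, exact permutation p = 0.0857) did not pass, and without mouse 1 their enriched shares were 0.151% and 0.0807%. The viable library of mouse 2 held 44.3% neutrophil-like cells (95% Wilson interval 42.2 to 46.4), and the difference without mouse 2 was -2.32 points against -12.8 points with it. With the mouse as a block, the exact permutation of 4 pairs cannot reach the threshold, and 0 classes passed.

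**Figure D1:**
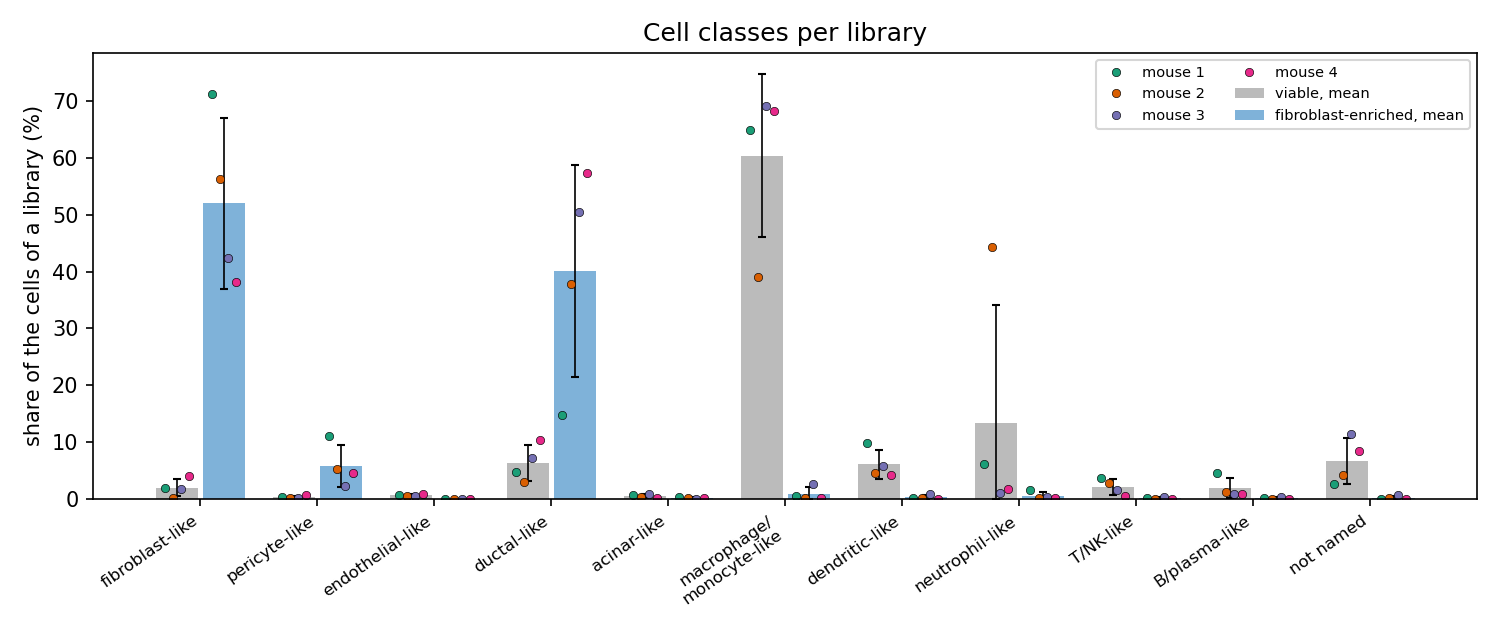
Percent of the cells of a library in each cell class, for the viable and the fibroblast-enriched fraction. Bars are means over 4 mice, whiskers are SD, and points are single libraries: fibroblast-like cells averaged 52.0% of the enriched libraries and 1.97% of the viable ones.

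Ductal-like cells fell into 8 clusters that differed in Epcam, the gene of a sorted surface antigen. A cluster of 412 cells came to 98.3% from the viable libraries, and 96.8% of its cells had an Epcam UMI. Only 7 of its cells were in the enriched libraries, 3, 0, 2 and 2 in mice 1 to 4. Clusters of 1330, 612, 294 and 251 cells came to between 95.6% and 99.8% from mouse 4, and an Epcam UMI was present in 0.327% to 3.61% of their cells. The remaining 3 clusters, of 800, 443 and 340 cells, had an Epcam UMI in 12.5%, 9.48% and 32.6% of cells and came to 80.0%, 76.3% and 72.1% from a single mouse. The marker set of ductal cells in epithelial-to-mesenchymal transition scored highest in the clusters of 612, 443 and 251 cells, although the ductal marker Tff1 led the genes of the cluster of 443.

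RNA levels averaged over all cells of a library followed the same sort. Dcn, a small leucine-rich proteoglycan of connective tissue and a marker used to name the fibroblast class, stood at 52.0 ± 19.7 UMIs per 10000 (SD, n = 4) in the enriched libraries and 1.71 ± 1.502 in the viable ones. Lyz2, the lysozyme gene of myeloid cells, stood at 2.25 ± 2.50 and 139 ± 34.5, a log2 change of -6.67 ± 0.82 (limma adjusted p = 0.000158). Ptprc, which encodes CD45, changed by -3.92 ± 0.30 on the log2 scale (limma adjusted p = 1.67e-05), from 2.23 ± 0.737 to 0.0558 ± 0.0581. Epcam changed by -2.18 ± 0.27 (limma adjusted p = 0.00016), from 0.693 ± 0.214 to 0.0763 ± 0.0620. Cd74, the invariant chain that guides MHC class II molecules, stood at 4.1985 ± 3.92 in the enriched libraries and 131 ± 35.3 in the viable ones (log2 change -5.26 ± 0.50, limma adjusted p = 4.11e-05). Without mouse 3 the enriched mean was 2.26 for Cd74, 1.12 for Lyz2 and 0.0458 for Epcam. Without mouse 1 the enriched mean of Ptprc was 0.0343, and without mouse 4 the viable mean of Dcn was 1.07.

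Both measured sort antigens were lower in the enriched fraction, and Pecam1, which encodes CD31, lay under the level filter. All 8 tested MHC class II genes were lower, by limma at adjusted p below the threshold, and 8 of 10 MHC class I pathway genes were lower with 2 not past it. The 4 tested co-stimulatory genes were lower, among them Cd86 (0.0234 ± 0.0291 against 0.890 ± 0.134, with an enriched mean of 0.00929 without mouse 3). Of 5 coinhibitory ligand genes 3 were lower and Cd276 was higher. The camera test of MHC class II gave an adjusted p of 4.23e-07 with its preset correlation and an adjusted p of 0.352 with an estimated correlation, and no list passed in the latter form. Extracellular matrix genes were higher for 19 of 20 members, complement genes for 7 of 8, contractile genes for 6 of 7 and mesothelial genes for all 3 tested, with the remainder not past the threshold. The corresponding camera adjusted p was 6.06e-06 for matrix, 0.00617 for complement, 0.00988 for contractile and 0.10017 for mesothelial genes, and each had an adjusted p of 0.451 with an estimated correlation. Examples were Sparc (54.7 ± 19.6 against 2.50 ± 2.29, log2 4.77 ± 0.61, with a viable mean of 1.41 without mouse 4) and Serping1, the C1 inhibitor (15.9 ± 6.06 against 0.566 ± 0.426, log2 4.86 ± 0.58).

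Other lists moved in both directions. Cytokine and chemokine genes had 4 higher, 2 lower and 6 not past, with Il33 higher by 3.65 ± 0.30 and Cxcl2 changed by -4.70 ± 0.46. TGF-beta targets had 5 higher and 2 lower of 9 (1 lower with the mouse as a block), JAK-STAT and NF-kB genes 3 higher and 4 lower of 12 (camera adjusted p = 0.0743, and 0.0487 with the mouse as a block, with an adjusted p of 0.477 at an estimated correlation), hypoxia and glycolysis genes 3 and 2 of 15, and stress and early response genes 4 and 4 of 14. Interferon-gamma genes had 1 higher and 4 lower of 11, type I interferon genes 1 lower of 7, and proliferation genes 2 higher of 8. Adjusted over the list alone, the counts were the same except for MHC class I (9 lower) and hypoxia and glycolysis (1 lower). Over 8164 tested genes, limma placed 3296 higher and 1499 lower in the enriched fraction. The median change was 0.246, and after centring each library on its median gene the counts were 2159 higher and 2191 lower.

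Fibroblast-like cells of the enriched libraries were then divided into subtypes, clustered without any of the fixed gene lists and named from markers that hold no MHC class II gene. Inflammatory (iCAF-like) cells made up 56.1% ± 19.2 (SD, n = 4), myofibroblastic (myCAF-like) cells 21.9% ± 6.79 and antigen-presenting (apCAF-like) cells 18.5% ± 11.3. The apCAF-like cluster held 742 cells, of which mice 1 to 4 gave 27, 265, 40 and 410. Its name rests on marker RNA, and whether its cells are fibroblasts, mesothelial or epithelial cells was not settled by these markers. A cluster of 200 cells met no naming rule, and 199 of them came from mouse 2. Some iCAF-like and myCAF-like clusters of the enriched libraries also came largely from 1 mouse. Mouse 4 gave 400 of 525 cells of a myCAF-like cluster and mouse 2 gave 235 of 294 of another. Mouse 1 gave 744 of 996 cells of an iCAF-like cluster. Mice 2 and 4 gave 315 of 328 and 280 of 303 of others. A myCAF-like cluster of 134 cells and an iCAF-like one of 454 were more mixed. Class means can thus rest on different clusters in different mice. Beside its naming markers, the apCAF-like cluster was led by Upk3b, Upk1b and Gpm6a, genes of mesothelium, and by the keratins Krt7, Krt14 and Krt19, which were picked out after their values were seen. Among its 10 leading genes, 2 were its own markers and 2, Krt7 and Krt19, were markers of ductal cells. With 4000 variable genes in place of 2000, 0 cells met the apCAF-like rule, and 748 of the 789 apCAF-like cells of both fractions were classed as not fibroblasts. At clustering resolution 1, 355 of the 789 stayed apCAF-like and 431 were in fibroblast clusters without a name.

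The comparison of apCAF-like cells with the other fibroblast-like cells asked whether MHC class II RNA marks a subset of fibroblasts. All 6 tested genes of the class II list were higher in apCAF-like cells in 4 of 4 mice. Cd74 (ENSMUSG00000024610, GRCm38 chromosome 18, 60803848 to 60812652) stood at 19.7 ± 8.90 UMIs per 10000 (SD, n = 4) against 0.337 ± 0.307, a log2 change of 5.70 ± 0.51 (limma adjusted p = 0.000125). H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419), a class II beta chain, stood at 4.81 ± 1.99 against 0.227 ± 0.156, a change of 3.96 ± 0.38 (limma adjusted p = 0.000175). H2-Eb1 (ENSMUSG00000060586, chromosome 17, 34305867 to 34316674) stood at 3.03 ± 1.23 against 0.0993 ± 0.0595, a change of 3.95 ± 0.28, and H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) at 2.55 ± 1.22 against 0.0834 ± 0.0757, a change of 3.83 ± 0.37. Without mouse 4 the mean of Cd74 in the other fibroblast-like cells was 0.216. Among the other fibroblast-like cells, Cd74 was at 5.58 UMIs per 10000 in an iCAF-like cluster of 220 cells, 154 from mouse 2 and 64 from mouse 4, and between 0.0258 and 0.186 in every other cluster.

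H2-DMa and H2-DMb1, which load peptides onto class II molecules, were higher by 1.63 ± 0.27 and 1.66 ± 0.24. Class II genes H2-DMb2, H2-Oa and Ciita lay under the level filter, and H2-Eb2 and H2-Ob were absent from the table of this fraction. Adjusted over the list alone, the count was again 6 of 6. The camera adjusted p was 1.92e-06 with the preset correlation, and an adjusted p of 0.185 followed with an estimated correlation. The 6 class II calls held when each mouse in turn was left out.

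**Figure D2:**
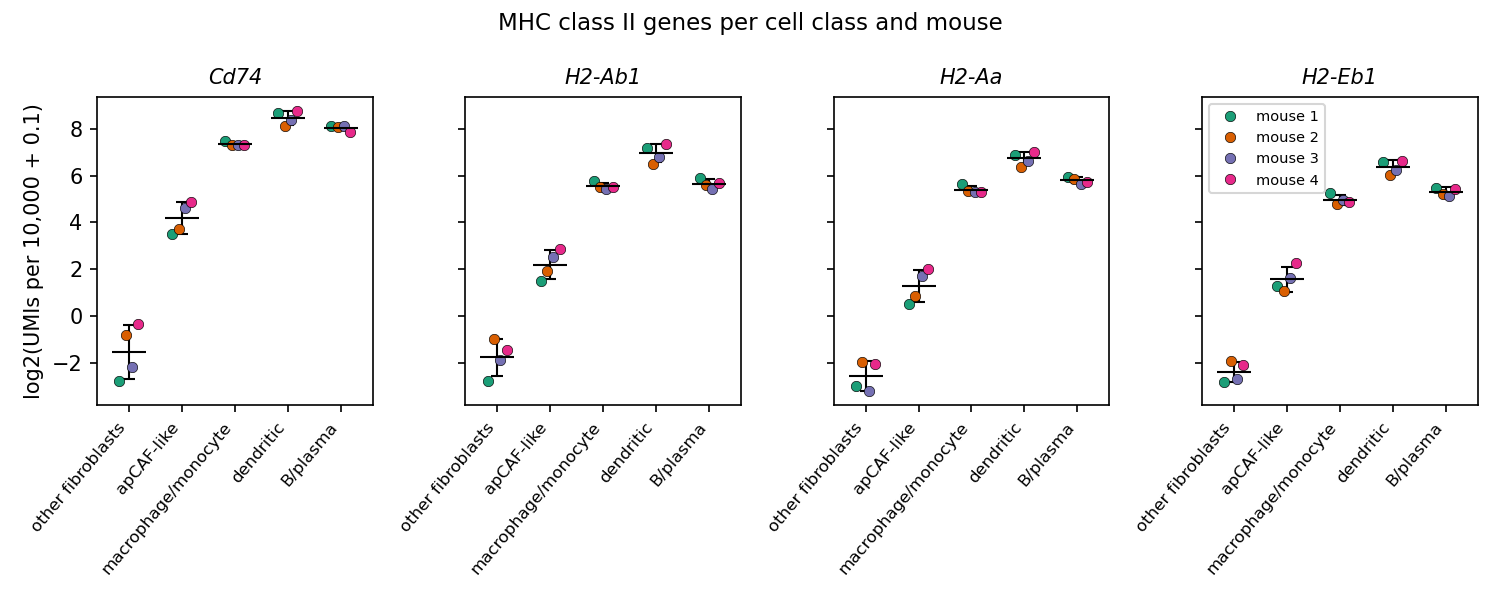
Levels of Cd74, H2-Ab1, H2-Aa and H2-Eb1 as log2(mean UMIs per 10000 + 0.1), for fibroblast classes of the fibroblast-enriched fraction and immune classes of the viable fraction. Points are mice, lines are means and whiskers are SD: apCAF-like cells lay above the other fibroblasts and below the immune classes in each of 4 mice.

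In the enriched libraries, 72.9% ± 11.6 (SD, n = 4) of apCAF-like cells had a Cd74 UMI, against 7.02% ± 3.39 of the other fibroblast-like cells. Median depth was 15506 and 8871.5 UMIs per cell. Ductal-like cells, taken as a class without class II RNA of its own, had a Cd74 UMI in 4.11% ± 2.21 of cells at a median of 12919 UMIs. After every cell was thinned to 3000 UMIs the shares were 57.0% ± 11.8 for apCAF-like, 3.38% for other fibroblast-like and 0.622% for ductal-like cells. For H2-Ab1 the shares were 67.7% ± 10.8 of apCAF-like and 8.49% ± 4.37 of other fibroblast-like cells. In the viable libraries a Cd74 UMI was present in 80.6% ± 3.82 of ductal-like cells and 81.7% ± 9.44 (n = 3) of the other fibroblast-like cells, so the share of cells with a Cd74 UMI does not separate these 2 classes there. The ductal-like class was a different mix of clusters in each fraction. Its cluster of 412 cells came to 98.3% from the viable libraries, where the class held 732 cells.

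Mesothelial and proliferation genes were also higher in apCAF-like cells. The first clustering could use the mesothelial genes. Upk3b and Upk1b led its cluster of 1019 cells in which the apCAF marker set scored highest. The rise of the mesothelial list is thus not independent of how the cells were grouped, and its p-values are not separate support. All 7 tested mesothelial genes rose, among them Upk3b (5.55 ± 2.01 against 0.0199 ± 0.0256, log2 5.50 ± 0.27, limma adjusted p = 2.12e-06), Upk1b (3.64 ± 0.697 against 0.0224 ± 0.0260, log2 4.94 ± 0.18) and Wt1, a transcription factor of mesothelium (3.73 ± 0.513 against 1.63 ± 0.275, log2 1.15 ± 0.14). Without mouse 4 the mean in the other fibroblast-like cells was 0.00795 for Upk3b and 0.0139 for Upk1b. The camera adjusted p for this list was 3.19e-09 and, as an adjusted p with an estimated correlation, 0.115. All 10 proliferation genes rose, including Cdc20 (0.899 ± 0.214 against 0.211 ± 0.0348, log2 1.66 ± 0.17), with a camera adjusted p of 4.82e-06 and an adjusted p of 0.219 with an estimated correlation. Of 15 hypoxia and glycolysis genes 6 rose, with Pkm at 14.3 ± 1.44 against 6.28 ± 2.24 and Tpi1 at 5.70 ± 0.512 against 2.49 ± 0.686, 1 fell and 8 did not pass. The glycolysis list did not pass camera (adjusted p = 0.0804, and an adjusted p of 0.374 with an estimated correlation), and with the mouse as a block 8 of its genes rose and 2 fell.

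Matrix genes fell in apCAF-like cells: 15 of 20 were lower and 5 did not pass. Postn, a matricellular protein, stood at 0.175 ± 0.0780 against 5.34 ± 2.01 (log2 -4.27 ± 0.28, limma adjusted p = 1.74e-05), Col8a1 at 0.0865 ± 0.0517 against 2.30 ± 0.332 (log2 -3.72 ± 0.20) and Fbn1 at 0.998 ± 0.342 against 8.37 ± 3.14 (log2 -2.92 ± 0.28). This list passed camera with the preset correlation (adjusted p = 5.41e-10) and with an estimated correlation (adjusted p = 0.00533), but in the fit with the mouse as a block the latter adjusted p was 0.0621. Cytokine and chemokine genes had 7 lower, with Ccl11, an eosinophil chemokine, at 0.0652 ± 0.0633 against 5.13 ± 3.38 (log2 -4.77 ± 0.48, with a mean of 0.0377 in apCAF-like cells without mouse 1), and 1 higher, Cxcl5 (log2 2.51 ± 0.60, limma adjusted p = 0.0181, and 0.0776 without mouse 3, and it also missed the threshold without mouse 4). Contractile genes had 4 lower of 7 and TGF-beta targets 5 lower and 1 higher of 10.

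MHC class I pathway genes had 5 higher of 10, led by Psmb8 (log2 0.95 ± 0.14), a subunit of the immunoproteasome, with a camera adjusted p of 0.0087 and an adjusted p of 0.374 with an estimated correlation. Interferon-gamma genes had 4 higher and 1 lower of 11, with Gbp2, a guanylate-binding protein, at 1.515 ± 0.384 against 0.317 ± 0.0893 (log2 1.94 ± 0.19, limma adjusted p = 0.000202). Type I interferon genes had 1 higher of 6. In the complement list Cfb rose by 1.02 ± 0.22, while C4b and Serping1 changed by -1.75 ± 0.33 and -1.55 ± 0.19, and 5 members did not pass. Stress and early response genes had 4 lower of 14, JAK-STAT and NF-kB genes 2 lower of 12 and coinhibitory ligands 1 lower of 3. The camera adjusted p of the coinhibitory list was 0.0610, and 0.0381 with the mouse as a block, which also placed Cd276 lower. With an estimated correlation the adjusted p was 0.185, and 0.252 with the block. The block moved the count of lower interferon-gamma genes from 1 to 2, of higher cytokine genes and TGF-beta targets from 1 to 2 each, and of higher JAK-STAT and NF-kB genes from 0 to 1. The only co-stimulatory gene above the filter, Tnfsf9, stood at 0.242 ± 0.0571 against 0.386 ± 0.152 and did not pass (limma adjusted p = 0.208).

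Adjusted over the list alone, matrix genes had 16 lower, glycolysis genes 9 higher and 2 lower, TGF-beta targets 6 lower, contractile genes 1 higher, coinhibitory ligands 2 lower, and JAK-STAT and NF-kB genes 2 higher and 4 lower. The other lists kept their counts. Over 6901 genes tested by limma, 792 were higher and 396 lower, and after centring on the median gene 679 and 493. Of 53 named genes past the threshold, 44, 44, 41 and 39 still passed without mouse 1, 2, 3 and 4.

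The iCAF-like cells were compared with the rest of the fibroblast-like cells, a group that includes the apCAF-like cells. Complement gene C4b stood at 10.2 ± 3.06 UMIs per 10000 (SD, n = 4) in iCAF-like cells against 2.29 ± 1.01 (log2 2.15 ± 0.29, limma adjusted p = 0.00626), and the limma adjusted p was 0.0598 without mouse 4 and also over the threshold without mouse 1. Chemokine genes Cxcl1 and Ccl7, which draw neutrophils and monocytes, rose by 1.98 ± 0.30 and 1.66 ± 0.18 on the log2 scale. Cell cycle gene Cdc20 stood at 0.0370 ± 0.00692 against 0.786 ± 0.229 (log2 -2.66 ± 0.17, limma adjusted p = 0.000133), and contractile genes Actg2 and Myl9 changed by -2.42 ± 0.24 and -1.73 ± 0.18.

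In this comparison 4 of 8 complement genes were higher and none lower (5 when adjusted over the list alone), as were 4 of 12 JAK-STAT and NF-kB genes (5 over the list alone), with Tnfaip6, an inflammation-induced hyaluronan-binding protein, up by 1.93 ± 0.28. Cytokine genes had 4 higher and 1 lower of 11. All 8 proliferation genes were lower, 7 with the mouse as a block, where Cdk1 no longer passed, and 6 of 7 contractile genes were lower. A cluster of 134 cells led by cell cycle genes such as Cdc20 and Mki67 was named myCAF-like and so lay in the rest, so the assignment of clusters set part of the proliferation difference. The lists passed camera with the preset correlation, with adjusted p of 0.000218 for complement, 0.000531 for JAK-STAT and NF-kB, 0.00477 for cytokines, 5.33e-08 for proliferation and 0.000218 for contractile genes. With an estimated correlation the same lists had adjusted p of 0.244, 0.146, 0.146, 0.181 and 0.181. TGF-beta targets had 2 lower of 10, and 4 with the mouse as a block, led by Tgfb1 (log2 -1.92 ± 0.23). Hypoxia and glycolysis genes had 5 lower, among them Pkm and Gapdh, and 1 higher, Adm, of 14. Matrix genes had 2 higher and 1 lower of 21 and stress and early response genes 1 higher of 14. No member of the MHC class I, co-stimulatory, coinhibitory, interferon-gamma and type I interferon lists passed. With the mouse as a block, Iigp1 and Irf7 of the interferon lists were higher, stress genes had 2 higher and 1 lower, hypoxia and glycolysis genes 2 higher and matrix genes 0 lower. Adjusted over the list alone, cytokine genes had 5 higher and 2 lower, hypoxia and glycolysis genes 2 higher and 8 lower, matrix genes 3 higher, TGF-beta targets 5 lower, class II genes 6 lower and mesothelial genes 5 lower.

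MHC class II genes had 4 of 6 lower and mesothelial genes 4 of 6, with Cd74 changed by -3.85 ± 0.77 and Upk3b by -3.97 ± 0.34. With 4000 variable genes, where the rest of the fibroblasts held no apCAF-like cells, Cd74 was 1.85 higher in iCAF-like cells, in the opposite direction (limma adjusted p = 0.205). Of 6843 genes tested by limma, 120 were higher and 352 lower. With the mouse as a block these counts were 191 and 557, and after centring on the median gene they were 165 and 166. Without mouse 1, 2, 3 and 4, 21, 17, 19 and 12 of the 39 named genes past the threshold still passed, and Ccl7, Cdc20, Upk3b, Actg2, Myl9 and Tgfb1 passed each time.

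In myCAF-like cells, 5 of 8 contractile genes and 5 of 10 TGF-beta targets were higher than in the rest of the fibroblast-like cells, and none of these calls held without mouse 4. Actg2, a smooth muscle actin, stood at 1.58 ± 0.929 UMIs per 10000 (SD, n = 4) against 0.0501 ± 0.0109 (log2 3.35 ± 0.29, limma adjusted p = 0.00182). Myl9, a myosin light chain, was higher by 2.51 ± 0.28 and Tgfb1, which encodes transforming growth factor beta 1, by 2.46 ± 0.21, from 0.35983 ± 0.0881 to 2.47 ± 0.742. The chemokine gene Cxcl14 was higher by 3.17 ± 0.35, and Inhba, an activin subunit, by 2.54 ± 0.33.

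Contractile genes had 5 higher of 8 (7 adjusted over the list alone) with a camera adjusted p of 4.81e-07 and an adjusted p of 0.113 with an estimated correlation. TGF-beta targets had 5 higher of 10 (6 over the list alone), and their camera adjusted p was 7.73e-06 with the preset and 0.0383 with an estimated correlation. In the fit with the mouse as a block the latter adjusted p was 0.146. Matrix genes had 4 higher of 21, among them Col8a1 (log2 2.46 ± 0.46) and Bgn, a proteoglycan (59.4 ± 6.77 against 27.1 ± 4.85, log2 1.14 ± 0.16). Lower genes included Cxcl1 (log2 -1.69 ± 0.23), Ccl7 (log2 -1.68 ± 0.19) and Cd74 (log2 -4.63 ± 0.82). MHC class II genes had 3 lower of 5, mesothelial genes 4 lower of 6 and MHC class I pathway genes 3 lower of 10, with 5 of the last with the mouse as a block. The rest included the apCAF-like cells, with Cd74 at 22.7 UMIs per 10000. Cd74 was between 0.0430 and 0.0559 in myCAF-like clusters. In iCAF-like clusters it was between 0.0461 and 0.186, apart from the cluster at 5.58. The lower class II and mesothelial calls need therefore not be a trait of myCAF-like cells. Cytokine genes had 3 lower and 1 higher of 12, complement genes 1 lower of 8, and 3 with the block. JAK-STAT and NF-kB genes had 1 lower of 12, stress and early response genes 1 lower of 14, hypoxia and glycolysis genes 1 higher of 14 and proliferation genes 1 higher of 9. No member of the co-stimulatory, coinhibitory or interferon lists passed. With the mouse as a block, Irf7 was lower, and the camera adjusted p of type I interferon genes was 0.00831 in place of 0.0758, with an adjusted p of 0.172 at an estimated correlation. The block also left 0 proliferation genes and 0 hypoxia and glycolysis genes higher and placed Adm lower. Adjusted over the list alone, interferon-gamma genes had 2 lower, stress genes 4 lower, hypoxia and glycolysis genes 1 lower and cytokine genes 2 higher, class II genes had 4 lower, mesothelial, MHC class I, complement, cytokine and JAK-STAT and NF-kB genes 5 lower each, and proliferation genes 4 higher. Of 6842 genes tested by limma, 124 were higher and 75 lower, and after centring 99 and 93. Of the 31 named genes past the threshold, 18, 8, 8 and 0 still passed without mouse 1, 2, 3 and 4, and Actg2 had a limma adjusted p of 0.0569 without mouse 4.

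Whether apCAF-like cells carry the genes of professional antigen-presenting cells was asked against macrophage/monocyte-like, dendritic-like and B-cell/plasma-like cells of the viable libraries. Class II RNA in apCAF-like cells was far below that of the immune classes. Cd74 stood at 19.7 ± 8.90 UMIs per 10000 (SD, n = 4) against 162 ± 9.53 in macrophage/monocyte-like cells (log2 -3.15 ± 0.27, limma adjusted p = 2.22e-06). In dendritic-like cells it stood at 362 ± 71.9 (log2 -4.29 ± 0.27, limma adjusted p = 2.40e-08) and in B-cell/plasma-like cells at 263 ± 19.2 (log2 -3.85 ± 0.26, limma adjusted p = 4.02e-07). H2-Aa was also lower, with log2 changes of -4.12 ± 0.28, -5.45 ± 0.28 and -4.51 ± 0.28 in the same order.

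Every tested class II gene was lower in apCAF-like cells, 7 of 7, 9 of 9 and 9 of 9 in these comparisons. The camera adjusted p was 2.06e-05, 1.18e-08 and 6.66e-10, and with an estimated correlation the adjusted p was 0.207, 0.162 and 0.0806. Co-stimulatory genes, which give T cells their second signal, were lower for 4 of 4 against macrophage/monocyte-like cells, 5 of 5 against dendritic-like cells and 2 of 4 against B-cell/plasma-like cells. Their camera adjusted p was 0.000638, 0.000142 and 0.00616, and with an estimated correlation the adjusted p was 0.0818, 0.0705 and 0.0806. Icosl (0.0434 ± 0.0727 against 0.187 ± 0.140) and Tnfsf9 (0.242 ± 0.0571 against 0.327 ± 0.136) did not pass against B-cell/plasma-like cells. The Icosl mean of apCAF-like cells rested on mouse 1, with 27 such cells, and was 0.00724 without it. Pooled over cells, Icosl had 14 UMIs in apCAF-like cells, a level of 0.0117 against 0.170 in B-cell/plasma-like cells. Counts adjusted over the list alone were the same for both lists.

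Cd86 was not seen in apCAF-like cells: 0 UMIs among 11924991 UMIs of 742 cells. Set against the floor of 3 UMIs over the group, a level of 0.00252 per 10000, the pooled level in macrophage/monocyte-like cells (1.15), dendritic-like cells (1.38) and B-cell/plasma-like cells (0.723) was at least 457-fold, 550-fold and 287-fold higher. Cd80 and Cd40 each had 1 UMI in apCAF-like cells, a level of 0.000839 with an interval of 2.12e-05 to 0.00467. Pooled levels in dendritic-like cells were 0.743 for Cd80 and 0.568 for Cd40. Tnfsf9, the ligand of 4-1BB, had 322 UMIs in apCAF-like cells, a pooled level of 0.270 against 0.725 in macrophage/monocyte-like cells. Ciita, the transactivator of class II genes, had 9 UMIs in apCAF-like cells, a level of 0.00755 against 0.412 in dendritic-like cells. These intervals and floors cover counting error only. B-cell/plasma-like cells also held Lyz2 and C1qa, genes of myeloid cells, at pooled levels of 61.0 and 14.8. Macrophage/monocyte-like cells held them at 207 and 42.0. A Lyz2 UMI was in 72.0% of B-cell/plasma-like cells, so the levels of that class may include myeloid RNA.

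**Figure D3:**
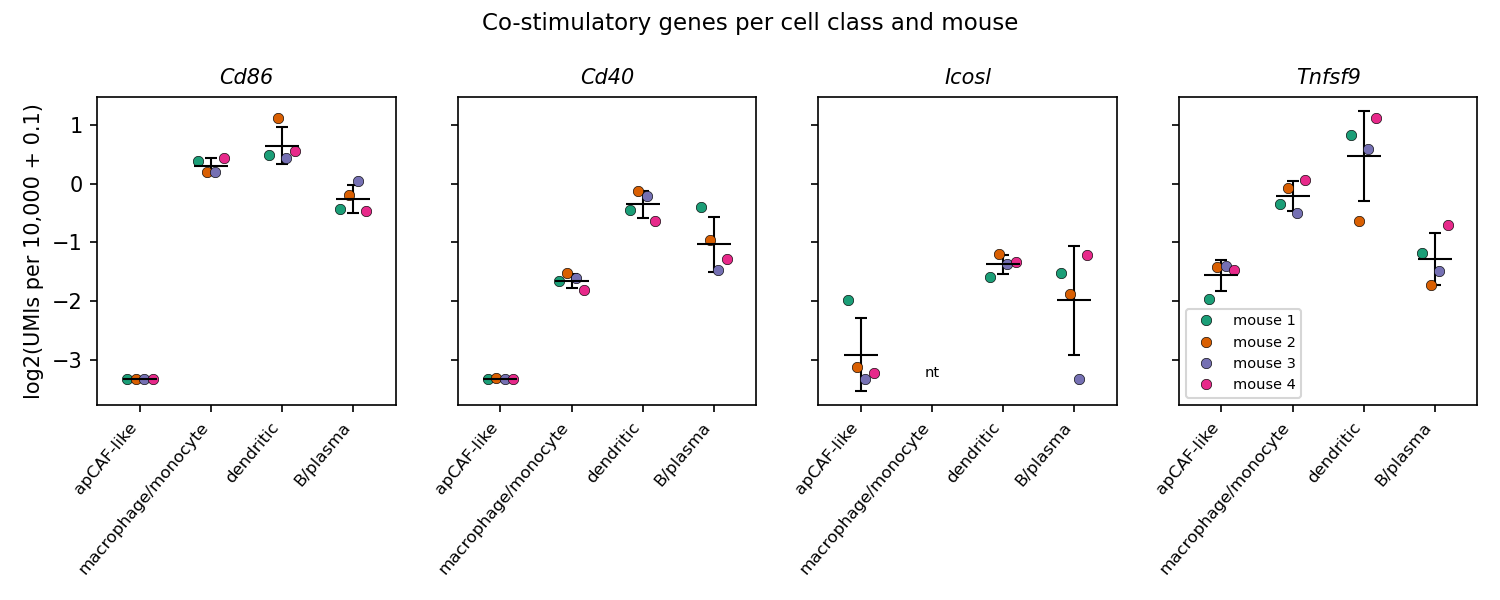
Levels of Cd86, Cd40, Icosl and Tnfsf9 as log2(mean UMIs per 10000 + 0.1), for apCAF-like cells of the fibroblast-enriched fraction and immune classes of the viable fraction. Points are mice, lines are means, whiskers are SD, and "nt" marks a gene under the level filter in that comparison: Cd86 was at 0 UMIs in apCAF-like cells of all 4 mice.

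Myeloid abundance separated the classes further. Lyz2 had 21 UMIs in apCAF-like cells, a pooled level of 0.0176 against 207 in macrophage/monocyte-like cells. Complement, matrix and mesothelial genes were higher in apCAF-like cells for 7 of 8, 16 of 18 and 7 of 7 tested members against macrophage/monocyte-like cells, where the matrix gene Fn1 was lower, and for 8 of 8, 18 of 18 and 7 of 7 against dendritic-like and against B-cell/plasma-like cells. With an estimated correlation the camera adjusted p of these lists was 0.207, 0.0818 and 0.207 against macrophage/monocyte-like, 0.162, 0.0705 and 0.162 against dendritic-like and 0.0806, 0.0548 and 0.0982 against B-cell/plasma-like cells. Against macrophage/monocyte-like, dendritic-like and B-cell/plasma-like cells, limma placed 3614, 3399 and 2689 genes higher and 1847, 1699 and 1145 lower in apCAF-like cells, of 7862, 7790 and 7895. Median changes were 0.262, 0.280 and 0.395, and after centring the counts were 2505, 2302 and 1956 higher and 2722, 2508 and 1615 lower. The sides came from different libraries, so fraction and cell class changed together in these comparisons.

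The last comparison asked whether fibroblast-like cells differ when recovered with and without the sort, with 4 enriched libraries and the 3 viable libraries that held at least 10 such cells. The lower genes were read one by one, with no list of myeloid genes tested. Lyz2 stood at 0.111 ± 0.0348 UMIs per 10000 (SD, n = 4) against 3.15 ± 1.10 (n = 3), a log2 change of -3.91 ± 0.23 (limma adjusted p = 0.000125). Ccl6, C1qa, Ctss, Il1b, C1qb, Tyrobp and C1qc were lower by the same test, with C1qa, a complement component of macrophages, at 0.00492 ± 0.00425 against 0.597 ± 0.0836 (log2 -2.73 ± 0.14, with an enriched mean of 0.00280 without mouse 4). Each moved the same way in 3 of 3 paired mice.

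Of 8076 genes tested by limma, 13 were lower and 0 higher, and 481 had an unadjusted p under 0.05. With the mouse as a block the counts were 76 lower and 51 higher. Without mouse 4, 6 genes were lower, and C1qb (limma adjusted p = 0.0546) and C1qc (limma adjusted p = 0.103) no longer passed. No member of a fixed list passed without the block. Adjusted over the list alone, 1 gene each of the TGF-beta, JAK-STAT and NF-kB and stress lists was higher. The camera adjusted p was 0.000127 for MHC class II and 0.00716 for stress genes, and with an estimated correlation both had an adjusted p of 0.858. Cd74 stood at 4.53 ± 3.61 in the enriched and 9.80 ± 6.17 in the viable fibroblast-like cells (log2 -1.46 ± 1.00, limma adjusted p = 0.846), and with the mouse as a block the adjusted p was 0.000262. The block also placed H2-Ab1, H2-Aa, H2-Eb1 and H2-DMa lower, at adjusted p of 8.76e-05, 0.000164, 9.51e-05 and 0.00216, with changes between -1.68 and -1.05 on the log2 scale. With the block, 4 stress genes, 3 JAK-STAT and NF-kB genes, 2 cytokine genes and 2 hypoxia and glycolysis genes were higher and 1 cytokine gene was lower.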

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

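The tests of immune-cell RNA and of UMI depth for the class II pattern were chosen after that pattern was seen, and the other tests here were not.

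MHC class II RNA in apCAF-like cells was weighed against technical sources. If the Cd74 excess of these cells came from free RNA or doublets of antigen-presenting immune cells, the fixed markers of those cells would come with it. The highest median, over macrophage/monocyte-like, dendritic-like and B-cell/plasma-like cells and over mice, of the marker level found over the level needed was 0.00985, far below 1, while single markers ran higher, with the highest of the 5 dendritic markers at 15.8, 3.71, 3.33 and 6.94 in mice 1 to 4. A higher UMI depth was also tested: after thinning to 3000 UMIs, the share of cells with a Cd74 UMI was higher in apCAF-like cells by at least 35.7 points in each mouse. Judged by these medians and the thinned shares, neither source accounts for the pattern as a whole. The high single dendritic markers were not explained. An immune-gene UMI was in 97 of 742 apCAF-like cells (13.1%) and 187 of 3454 other fibroblast-like cells (5.41%). Median depths were 15506 and 8871.5 UMIs. A part from immune-cell RNA is thus not excluded. Whether these cells are fibroblasts or mesothelial cells stays open, and the design holds no group that tests a biological explanation.

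Genes lower in fibroblast-like cells of the enriched fraction were the 13 past the threshold, with Lyz2 and C1qa among them. Free immune-cell RNA in the viable libraries predicts like levels in ductal-like and fibroblast-like cells there, and the median ratio over these genes was 2.12 (range 1.33 to 2.75), between the bound of 2 for that source and the bound of 4 against it, so it cannot be told apart from other sources. Doublets of a fibroblast with an immune cell would put the UMIs in few cells, but the median share of cells with a UMI was 1.02 times the Poisson share (range 0.934 to 1.10), which argues against them. No biological explanation was tested.

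Limma was run on each of the 35 splits of the libraries into groups of the same sizes. Only 1 split, the real one, gave as many genes for 7 comparisons. For the fractions the share was under 0.05 over all 35 splits, which ignore the pairing by mouse. Only 8 splits separate all pairs there, and the highest other count among them was 0. As 8 splits are too few for a share under 0.05, chance is not excluded with the pairing kept. The other 6 compare classes that were cut from the same expression values, which favours the real split, so the splits exclude nothing there. The real count and the highest other count were 4795 and 0 for the fractions, 1188 and 1 for apCAF-like, 472 and 5 for iCAF-like and 199 and 5 for myCAF-like cells against the rest. Against macrophage/monocyte-like, dendritic-like and B-cell/plasma-like cells they were 5461, 5098 and 3834, with 0 in every other split. For fibroblast-like cells between fractions, 2 of 35 splits gave as many genes, with 13 for the real one and 38 for the highest other. That other split separated 0 of the mouse pairs, so it compared mice rather than fractions. Among the 8 splits that separate all pairs, the real one included, the highest other count was 0, and 8 splits are too few for a share under 0.05.

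In 20 of 119 groups of 4 samples a sample stood apart from the other 3 by a gap above Dixon's 95% critical value, where chance gives about 1 in 20, or 5.95. Viable mouse 2 held 39.0% macrophage/monocyte-like cells (95% Wilson interval 36.9 to 41.1, others 65.0% to 69.2%) and 44.3% neutrophil-like cells (42.2 to 46.4, others 0.995% to 6.14%). Viable mouse 1 held 4.49% B-cell/plasma-like cells (3.80 to 5.29, others 0.878% to 1.12%). In the enriched libraries, macrophage/monocyte-like cells made up 2.61% in mouse 3 (1.38 to 4.88) and neutrophil-like cells 1.61% in mouse 1 (1.07 to 2.40). Of fibroblast-like cells, 84.6% were iCAF-like in mouse 1 (82.3 to 86.7, others 45.1% to 49.3%) and 13.8% were in the cluster without a name in mouse 2 (12.1 to 15.7).

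The enriched library of mouse 3, with 345 cells, stood apart over all cells in 5 class II genes. In UMIs per 10000 it held Cd74 at 10.01 (others 1.77 to 3.15), H2-Aa at 1.78 (0.296 to 0.438), H2-Ab1 at 2.68 (0.503 to 0.795), H2-DMa at 0.282 (0.0738 to 0.0830) and H2-DMb2 at 0.0834 (0.000861 to 0.0114). Over all viable cells, mouse 1 stood apart in H2-DMb2 at 1.27 (0.512 to 0.586) and H2-Oa at 0.36043 (0.133 to 0.149). In macrophage/monocyte-like cells mouse 1 had Cd74 at 176 (156 to 159) and H2-Aa at 49.6 (39.4 to 40.6). Tnfsf9 in apCAF-like cells was 0.157 in mouse 1 (0.260 to 0.276), and Cd86 in dendritic-like cells was 2.08 in mouse 2 (1.26 to 1.36). In B-cell/plasma-like cells Epcam was 0.666 in mouse 2 (0.0982 to 0.128) and H2-DMb1 was 1.33 in mouse 4 (1.81 to 1.87).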

How the results depend on the processing

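Chosen after the data were seen were median centring, naming by the subtype score alone, shares among named classes other than ductal-like, and leaving out the enriched library of mouse 3, apCAF-like cells or cells over 20% mitochondrial. Over all alternatives of the named genes, 4947 of 5470 values kept direction and side of the threshold, 505 kept only the direction, 12 newly passed and 6 reversed. The cause was not tested unless given.

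Genes higher in the enriched fraction numbered 3296, 5053 with no filter on low levels, where more genes were tested, and 2159 after median centring, and without the enriched library of mouse 3 they numbered 3080. With each mouse left out they ran from 2619 to 2913. The 3 higher and 6 lower cell classes became 0 and 0 with the mouse as a block and 0 and 0 without any 1 mouse, where the permutations are too few to pass. They became 2 and 5 of 10 classes at resolution 0.5, 2 and 6 of 10 with 1000 variable genes, 3 and 7 with cells under 1000 genes left out, and stayed 3 and 6 without cells over 20% mitochondrial. Among named classes other than ductal-like they were 2 and 5 of 9, and the fibroblast-like difference was 85.2 points in place of 50.035, where 5274 ductal-like and unnamed cells left the total.

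All 6 class II genes stayed higher in apCAF-like cells without each mouse, and 5 passed at fibroblast resolution 1. Over all lists, apCAF-like cells had 42 genes higher and 42 lower. In the viable fibroblasts, where fewer cells and mice were compared, they had 17 and 12, and without a mouse 25 to 33 higher, with 25 without mouse 4. For iCAF-like cells 16 were higher and 31 lower, 4 and 9 in the viable fibroblasts, 18 lower with 4000 variable genes, and 2 to 8 higher and 10 to 17 lower without a mouse. For myCAF-like cells 17 were higher and 16 lower, 9 and 3 with no filter, 11 and 6 with 4000 variable genes and naming by score alone, 1 and 1 in the viable fibroblasts, 9 lower with a pseudocount of 1, and 0 to 9 higher and 0 to 11 lower without a mouse, with 0 and 0 without mouse 4.

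With 4000 variable genes, where no cluster was named apCAF-like and 748 of the 789 apCAF-like cells were classed as not fibroblasts, the iCAF-like changes of Cd74 (1.85), H2-Aa (0.86), H2-Ab1 (0.58) and H2-Eb1 (0.93) and the myCAF-like change of H2-DMb1 (0.14) reversed to higher. In the viable fibroblasts the iCAF-like change of Osmr reversed to -0.12.

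Fibroblast-like cells between fractions had 0 genes higher and 13 lower, 51 and 76 with the mouse as a block, 1 and 20 with no filter, 0 and 15 without apCAF-like cells, and 6 to 13 lower without a mouse, with 6 without mouse 4. The block lost Bgn in iCAF-like cells (limma adjusted p = 0.0588) and Slc2a1 and Ccnb1 in myCAF-like cells (limma adjusted p = 0.0546 and 0.0834), and beyond the values given here and in the comparisons it changed no other call of a named gene past the threshold.

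After thinning to 3000 UMIs, a Cd74 UMI was in 57.0% of apCAF-like and 3.38% of other fibroblast-like cells, and an H2-Ab1 UMI in 40.7% and 3.57%, since fewer UMIs per cell were drawn. In the viable fraction, without thinning, the shares were 98.3% and 81.7% for Cd74 and 96.6% and 68.1% for H2-Ab1. They rest on 45 apCAF-like cells (n = 2 mice) and 172 other fibroblast-like cells (n = 3). Median depth was 14952 and 8932 UMIs. After thinning, the viable shares were 82.4% and 52.7% for Cd74 and 72.4% and 36.0% for H2-Ab1. Removal of called doublets was not run, and Scrublet called 68 of 19784 cells. A test with DESeq2, planned for tables of counts only, was not run since the deposited tables hold log values. The recovered UMI counts would have allowed a count model.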

Other observations

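The tests here were chosen before their results were seen. A cluster of 220 iCAF-like cells of the enriched libraries held Cd74 at 5.58 and H2-Ab1 at 2.45 UMIs per 10000, with a UMI in 42.7% and 49.1% of cells, and Upk3b in 10.0% of cells. Among all cells, a cluster of 633 cells met no naming rule. The macrophage marker set scored highest in it, with 8 markers detected, and Alox15, Saa3 and Prg4 led its genes. It went without a name because its 10 leading genes held 1 marker of another class, Saa3 of apCAF-like cells, and 0 of its own. Some clusters named macrophage/monocyte-like also had 0 own markers there, but 0 of another class.

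Cd74 RNA in fibroblast-like cells outside the apCAF-like cluster was set against mesothelial RNA, to ask whether cells with mesothelial-gene RNA hold it there too. After thinning to 3000 UMIs, 40 cells of mouse 2 and 60 of mouse 4 had a Cd74 UMI, and the odds ratio of a mesothelial-gene UMI in them against other cells was 3.81 and 2.94. Mice 1 and 3 had 6 and 4 such cells, too few for the test, and showed no excess (odds ratios 0.972 and 0). A UMI of any gene of the mesothelial list counted here. In the other fibroblast-like cells of the enriched libraries, the mean level was 1.63 for Wt1, 0.0199 for Upk3b and 0.0224 for Upk1b. Much of the count may therefore be Wt1, and single genes were not tested. The Cd74 RNA of these cells may thus go with UMIs of the pooled list in mice 2 and 4. Whether it goes with mesothelial genes other than Wt1 cannot be told from this test. Doublets with apCAF-like cells remain open as a source.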
